A study of Mus musculus with 2 samples.

How the data were processed

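Pancreatic RNA was measured on 2 Affymetrix mouse expression arrays, 1 for each of 2 groups of male C57BL/6J offspring. The groups differed in the diet of the dams between embryonic days 12.5 and 14.5, which was either a control diet or a diet deficient in threonine, an essential amino acid. Each group was represented by 1 pool of RNA from whole pancreas taken at 10 weeks of age, per the labels. The number of animals in each pool is not given in the sources used here. RNA had been extracted with TRIzol and converted to biotin-labelled cRNA with the GeneChip 3' IVT Express Kit, per the labels' protocols.

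The deposited values were a linear signal intensity per probe set, produced with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and scales each array as a whole. After 2% of the values were trimmed at each end, the mean signal was 500.0 on both arrays, the value that such scaling leaves. Because each array had been scaled to the same mean, a difference in total mRNA between the pools could not be seen, and every ratio is relative to the rest of its array. Detection calls were not used here, so a floor on low signals took their place.

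The table held 45101 probe sets, of which 64 were control probe sets and were kept out of the gene comparisons. Of the others, 34945 carried exactly 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. No gene was named from a probe set with several symbols. Names were checked through gene identifiers against a mouse RefSeq gene table of assembly GRCm38.p6. This matched 34741 of the probe sets with 1 symbol, and 204 kept the name of the annotation. No genome build is named for the array values, so no positions are given. Each gene was represented by its probe set with the highest mean log2 signal, which gave 18193 genes. Members of a gene list with no such probe set, among them Ins1, Mafa and Pcsk2, were not analysed here.

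Signals below the higher of the 60th percentiles of the 2 arrays, a signal of 264.9, were raised to that floor before log2 was taken. The log2 ratio was that of the threonine-deficient pool over the control pool. A gene was counted as higher or lower when the signals differed at least 2-fold. When 1 of the 2 signals lay at the floor the fold is a lower bound and is given as "at least". With 1 pool and 1 array per group there were no replicates, so no p-value, standard deviation between samples or test of a single gene could be given. The number of arrays limits the precision of every value.

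3 descriptions of error took the place of replicates. The log2 ratios of different probe sets of 1 gene were compared across genes, which covers probe and hybridisation noise only. The control transcripts added to the RNA or to the hybridisation mix were read in the same way. For single genes, the local spread was the scaled median absolute deviation of the log2 ratios of genes of like signal.

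47 gene lists covering the cell types a pancreas can hold, neighbouring tissues, and pathways of amino acid, protein and energy metabolism were fixed before the data were examined. The thresholds, the alternatives and the rule for naming genes were fixed at the same time. For each list with at least 4 members above the floor, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean signal in 50 bins. A list was said to stand apart when its median lay below percentile 2.5 or above percentile 97.5. This describes these 2 arrays and is not a test between diets.

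Genes were named by a rule with 3 parts. The first took the 15 genes with the highest and the 15 with the lowest log2 ratios among those above the floor on both arrays, at least 2-fold apart, at or above the 75th percentile of signal on at least 1 array, and with no other probe set going the opposite way. The second took the 5 brightest genes in each direction that were at the floor on the other array. The third took up to 4 members of each list with the largest absolute log2 ratios, together with the islet hormones and Asns, Ddit3, Trib3 and Atf4 whatever their values.

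The alternatives were centring on the median, removal of a loess trend of log2 ratio on signal, no floor, floors at the 50th and 75th percentiles, a pseudocount equal to the floor in its place, the median over all probe sets of a gene, and leaving out probe sets with a sharing suffix (_s_at, _x_at or _a_at), which marks possible sharing between transcripts. The procedure was tested on simulated data with known answers. In a simulated comparison of the threonine-deficient with the control pool run on 10620 genes, 52 of 100 genes set 2-fold apart and 90 of 99 set 4-fold apart were called. Of 10343 unchanged genes in that simulation, 40 were called. Its noise was set by hand for each signal level and not measured on these arrays, so these rates need not hold for the data. All 3 shifted lists stood apart, which the simulation had to reach in order to finish, as did 3 of 36 unshifted ones. The shifts set were larger in size than the medians found for the same lists in the data. Recovery of smaller list shifts was therefore not tested. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.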

Results

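Gene expression was measured in whole pancreas of 10-week-old male mice whose mothers had received a control or a threonine-deficient diet from embryonic day 12.5 to 14.5. The offspring were weaned at 3 weeks and kept on control diet, so the diets differed only before birth. There was 1 pooled RNA sample and 1 array per group. No value below has a replicate, and every difference is between these 2 pools.

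The arrays had been scaled to the same trimmed mean, and their median signals were 164.7 in the control and 183.8 in the threonine-deficient pool. The 20 brightest probe sets held 8.09% and 8.58% of all signal. Log2 signals of the arrays correlated across probe sets with a Pearson r of 0.843 over 45037 probe sets and 0.972 over the 15180 above the floor on both, although probe sets are not independent replicates. Of 18193 genes, 10758 lay above the floor on at least 1 array and 8834 on both.

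The comparison asked how the adult pancreas of offspring of threonine-deficient dams differed from that of control offspring. Transcripts of fat cells were lower in the threonine-deficient pool, with Car3, a carbonic anhydrase abundant in adipocytes, at 5434 against 14501 signal units. The islet hormone list was also lower as a whole, and its members ranged from a log2 ratio of −0.92 for Sst to −0.02 for Ppy. The digestive enzymes of acinar cells were slightly higher as a list, with a median log2 ratio of 0.10. Scd1, the desaturase that makes monounsaturated fatty acids, had the lowest ratio of the genes named for size that were above the floor on both arrays, and Car2, a carbonic anhydrase of duct cells, had the highest.

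In all, 138 genes were at least 2-fold higher and 94 at least 2-fold lower in the threonine-deficient pool, together 2.16% of the genes above the floor. Of these, 66 higher and 57 lower genes were above the floor on both arrays. The other 72 and 37 were at the floor on 1 array. Most genes, 9406 or 87.4%, were within 1.5-fold. The counts depended on the floor, and with it at the 75th percentile 23 genes were higher and 23 lower.

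**Figure D1:**
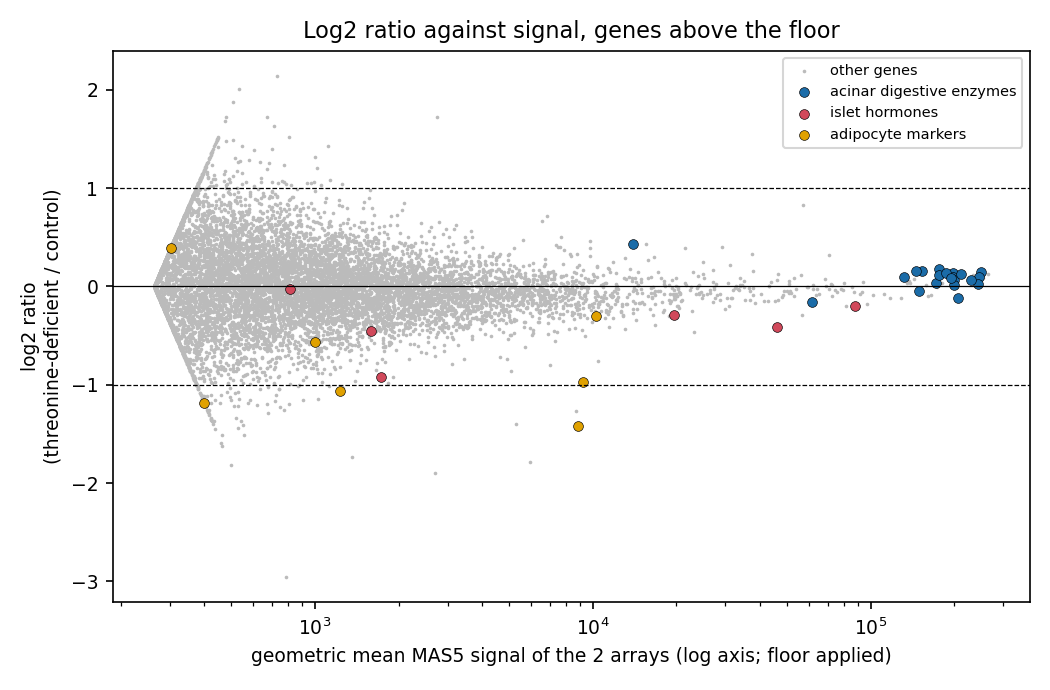
Log2 ratio of the threonine-deficient over the control pool (vertical axis) against the geometric mean MAS5 signal of the 2 arrays (horizontal log axis), with 1 point per gene above the floor and dashed lines at 2-fold. Acinar enzymes lie at the bright end close to 0, islet hormones lie below 0, and 3 of 7 adipocyte markers lie below the lower line.

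Repeat readings of the same gene limit what can be said of single genes. Over 3246 genes with a second probe set above the floor, the error per probe set was a standard deviation of 0.34 on the log2 scale. The log2 ratios of the probe set pairs correlated with a Pearson r of 0.0592 and a Spearman rho of 0.0398 across genes, which are not independent replicates, and 52.1% had the same sign. Among the 812 genes with the brightest second probe sets the error was 0.22 and 59.0% had the same sign. Of 30 genes at least 2-fold apart that had a second probe set above the floor, 19 had the same sign in it. 2 of them, Car3 and Ano6, were at least 2-fold apart in the same direction in both, and 2, Ankrd24 and Cpeb3, were at least 2-fold apart in opposite directions. Ano6, Ankrd24 and Cpeb3 lie outside the naming rule and were chosen after their values were seen.

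Among the genes higher in the threonine-deficient pool, Car2 had signals of 349 in the control and 1541 in the threonine-deficient pool, 4.42-fold higher. Its log2 ratio of 2.14 compares with a local spread of 0.36, and it was read by 1 probe set. Clcn5, a chloride/proton exchanger of endosomes, was 3.31-fold higher, and Polh, a DNA polymerase that copies past damaged bases, was 3.30-fold higher. In both genes the other probe sets lay below the floor. Siah1a, a ubiquitin ligase, was 3.10-fold higher, while its other probe sets gave log2 ratios of at least 0.39, from the floor, and 0.05. Tpd52l2 was 2.69-fold higher, with 0.27 and 0.14 in its other probe sets. The epithelial mucin gene Muc13 had a log2 ratio of 1.42 and the netrin receptor gene Unc5c one of 1.39. The remaining genes of this group were Zfp358, Sapcd2, Smg9, Rabgap1l, Fbxo36, Cyp2b13, Mapk1ip1 and Dnajc11, with log2 ratios from 1.49 for Zfp358 to 1.27 for Dnajc11. Cyp2b13 belongs to a family of closely similar genes, so its probe set may not be specific. Clcn5, Polh, Siah1a, Sapcd2, Muc13 and Mapk1ip1 were read by probe sets ending in _s_at or _x_at, which may be shared between transcripts.

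Genes at the floor in the control pool included Dbh, which encodes the enzyme that makes noradrenaline and was at least 3.29-fold higher. Snx22 was at least 3.66-fold, Sema6c at least 3.20-fold and Amhr2 at least 2.87-fold higher. Dennd6b was at least 4.02-fold higher in its brightest probe set, but its log2 ratio was −0.05 when the median over its probe sets was taken, a value read at the floor in the threonine-deficient pool. That brightest probe set and the one for Amhr2 ended in _x_at.

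Among the lower genes, Scd1 had signals of 10992 in the control and 3188 in the threonine-deficient pool, 3.45-fold lower. Its log2 ratio was −1.79 against a local spread of 0.17, and its dimmer probe set gave −0.83. Cyp2e1, a cytochrome P450 that metabolises ethanol, had a log2 ratio of −1.73. Car3 had −1.42 in its brighter and −1.69 in its other probe set. Atp5md, a subunit of mitochondrial ATP synthase, went from 8586 to 3244 (−1.40), and Abcc5, an export pump, from 13455 to 5584 (−1.27). Mmd had −1.41, with −0.99 and −0.12 in its other probe sets, which were at the floor in the threonine-deficient pool. St3gal5, the ganglioside GM3 synthase, had −1.37. Ttc7 had −1.51 but −0.34 and −0.08 in its other probe sets, both at the floor in that pool and so bounds, and Nt5c3b had −1.44 but −0.03. The rest were Exph5, Phldb1, Nabp2, Tmem94, Atmin and Fam161a, with log2 ratios from −1.52 for Exph5 to −1.26 for Fam161a. The rule passed over 3 lower genes and 1 higher gene because another probe set went the opposite way, among them Fen1, a nuclease of DNA replication, with −2.96 in its brightest probe set. Genes at the floor in the threonine-deficient pool included Pck1, a key enzyme of gluconeogenesis and of glycerol synthesis in fat, which was at least 3.53-fold lower, with −0.46 in another probe set that was also at the floor there. Klk1b21, from a kallikrein family of closely similar genes, was at least 3.08-fold lower, the junctional protein gene F11r at least 3.02-fold, Msgn1 at least 2.73-fold and Efcc1 at least 2.64-fold lower.

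Of the 47 lists, 39 had enough members above the floor to describe. Of these, 3 stood apart as higher and 5 as lower, 8 in all, where 2 would do so if members of a list varied like random genes. Members of a list can vary together, and lists can share members, as Gcg is in the islet hormone and alpha cell lists. The comparison of 8 with 2 can therefore overstate the excess. Adipocyte markers, islet hormones and acinar digestive enzymes stood apart under 8 of 8 alternatives.

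**Figure D2:**
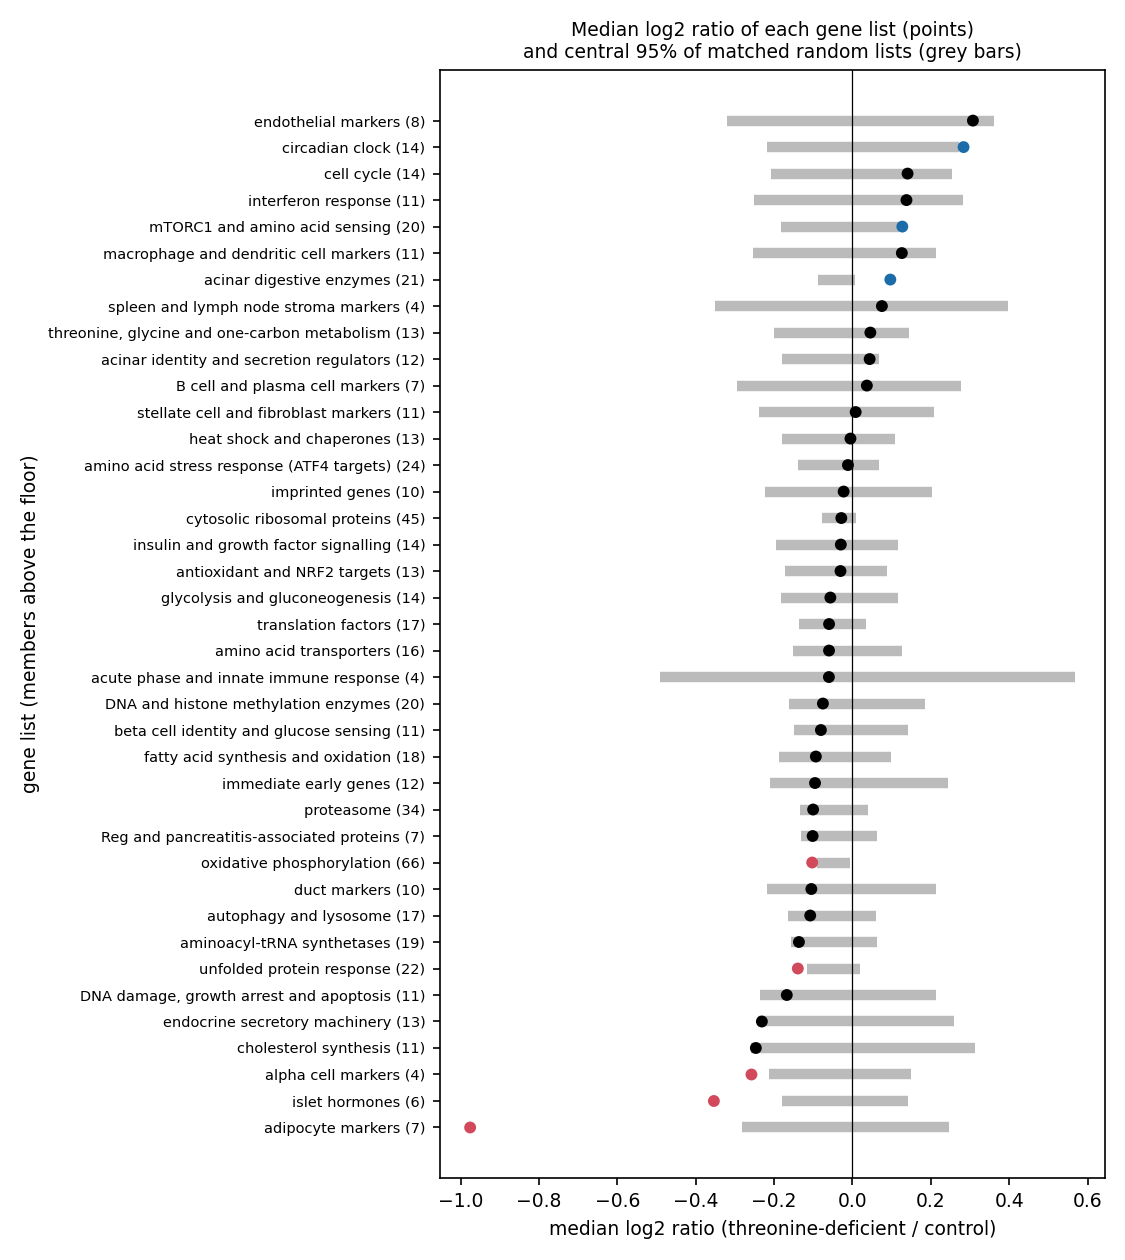
Median log2 ratio (horizontal axis, threonine-deficient over control) of each described gene list (vertical axis, members above the floor in brackets), with grey bars for the central range of 10000 matched random lists. Blue points mark the 3 lists that stood apart as higher, red points the 5 that stood apart as lower and black points the rest, and the adipocyte list is farthest from 0 at −0.98.

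In the exocrine pancreas, the list of acinar digestive enzymes had a median log2 ratio of 0.10 over 21 members, 18 positive and 3 negative, above the random range of −0.09 to 0.01. Its members included Amy1, an amylase (0.43), the elastase Cela2a (0.18), the chymotrypsin-like protease Ctrl (0.16) and chymotrypsin C, Ctrc (−0.16). Several of these belong to families of similar genes whose transcripts 1 probe set can share. Many of these signals lay close to the array maxima of 263446 and 275999, where differences can be compressed, so their size is uncertain. Acinar regulators had a median of 0.04 over 12 members and did not stand apart, except as higher with the median over probe sets (0.08). The transcription factor Ptf1a had −0.27 and Bhlha15, which governs the secretory apparatus, 0.29. Reg and pancreatitis-associated proteins had a median of −0.10 over 7 members, with Reg3a at −0.74 and Reg1 at 0.12.

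In the endocrine pancreas, all 6 hormone transcripts above the floor had lower signals in the threonine-deficient pool. The list median was −0.35, at percentile 0.03 of random lists whose range was −0.18 to 0.14. Somatostatin (Sst) went from 2373 to 1252, a log2 ratio of −0.92 against a local spread of 0.25. Islet amyloid polypeptide (Iapp), which is secreted with insulin, went from 52958 to 39770 (−0.41, local spread 0.11). Its other probe sets gave −0.51, −0.39 and 0.00. Peptide YY (Pyy) had −0.45, glucagon (Gcg) −0.29, insulin 2 (Ins2) −0.20 and pancreatic polypeptide (Ppy) −0.02. The Ins2 probe set may also read the near-identical Ins1. Ghrl lay below the floor on both arrays. The 24 probe sets for polyadenylated control transcripts had log2 ratios from −0.39 to 0.53, a range that includes the values of Gcg, Ins2 and Ppy. Its ends came from dim probe sets: the 6 dap probe sets, closer to Gcg in signal, ranged from −0.06 to 0.16, which leaves Gcg and Ins2 outside. The 18 hybridisation controls ranged from −0.32 to 0.06, which includes Gcg, Ins2 and Ppy. The low end of that range came from a bright probe set (52839 to 42269), and the next lowest value was −0.20. The local spread was 0.12 for Gcg and 0.10 for Ins2.

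Alpha cell markers had a median of −0.26 over 4 members, Gcg among them, which stood apart, but not with no floor or with the median over probe sets (−0.13). Endocrine secretory machinery had a median of −0.23 with 11 of 13 members negative and, at percentile 3.05, did not stand apart, although it did as lower under 4 of 8 alternatives. Its members included chromogranin A, Chga (−0.50), the granule protein Ptprn (−0.56) and the vesicle protein Vamp2 (0.85). Beta cell identity and glucose-sensing genes had a median of −0.08 over 11 members. The glucose transporter gene Slc2a2 was at least 2.12-fold lower, from 563 to 232, and the zinc transporter gene Slc30a8 had −0.57, G6pc2 −0.44 and the receptor gene Glp1r 0.65. Of the serotonin and pregnancy-associated islet genes, 3 were above the floor.

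**Figure D3:**
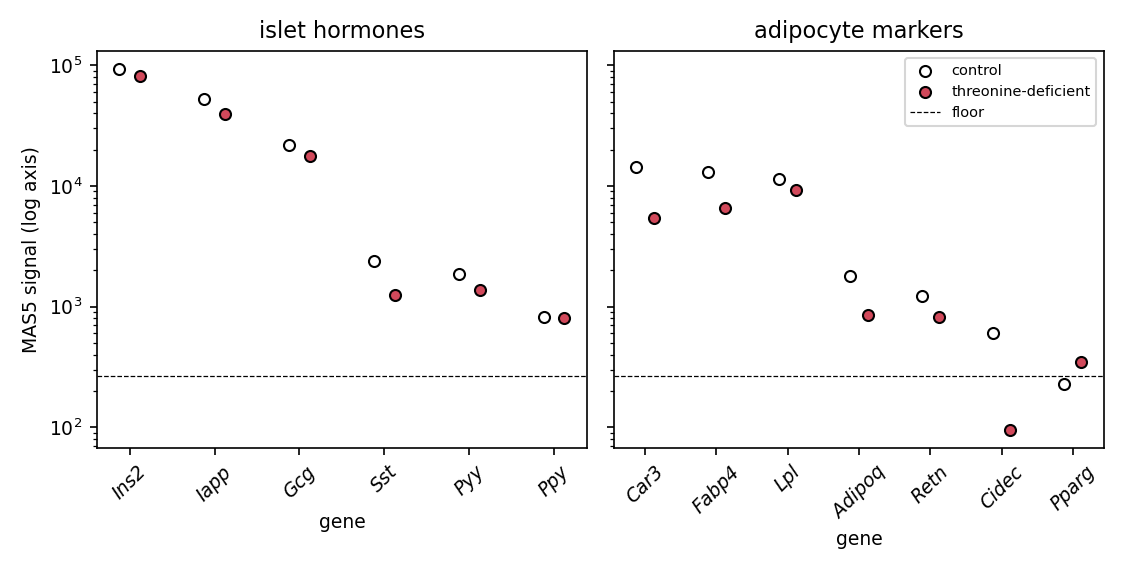
MAS5 signal (vertical log axis) of each islet hormone gene and adipocyte marker above the floor (horizontal axis), with open points for the control pool, red points for the threonine-deficient pool and a dashed line at the floor of 264.9. The red point is below the open point for 6 of 6 hormones and for 6 of 7 adipocyte markers.

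Adipocyte markers had the lowest list median, −0.98 over 7 members, at percentile 0.00 of 10000 random lists, whose central range was −0.28 to 0.25. Besides Car3, the adipokine gene Adipoq went from 1787 to 855 (−1.06) and the fatty acid carrier gene Fabp4 from 12966 to 6592 (−0.98), with −0.47 in another probe set of Fabp4 and −0.15 in one that was at the floor in the threonine-deficient pool. The lipid droplet gene Cidec was at least 2.28-fold lower. The remaining members were Retn (−0.57), Lpl (−0.30) and Pparg (0.39 as a bound), a nuclear receptor gene at the floor in the control pool. With a pseudocount in place of the floor the median was −0.45, and with the median over probe sets −0.57.

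Neither lipid list stood apart. Fatty acid synthesis and oxidation had a median of −0.09 over 18 members, 13 negative and 5 positive. Its members of largest absolute ratio were Scd1 at −1.79, Thrsp, a regulator of lipogenesis, at −0.97, Angptl4 at −0.77 and Fasn at −0.63. Cholesterol synthesis had a median of −0.25 with 9 of 11 members negative, at percentile 3.04, but stood apart as lower after loess centring (−0.28). Sqle, which makes squalene epoxide, had −1.04. Cyp51 had −0.55 and Lss −0.47, although Lss had 0.28 without probe sets of a sharing suffix.

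Markers of the other cell types did not stand apart. Duct markers had a median of −0.11 over 10 members, although Car2 was high and Sox9 had 0.89. Endothelial markers had a median of 0.31, with 8 of 8 members positive, among them Pecam1 (0.57) and Tek (0.42), at percentile 94.4. Stellate cell and fibroblast markers had a median of 0.01, macrophage and dendritic cell markers 0.13, and stroma of spleen and lymph node 0.08. B cell and plasma cell markers had a median of 0.04 and went both ways. The immunoglobulin heavy chain gene Ighm had −1.90 in its brightest probe set, with its other probe sets from −0.94, a bound from the floor, to 0.57. Mzb1 had −1.12 and Jchain −0.79, and Cd22 was at least 1.83-fold higher. Smooth muscle, T cell, neutrophil and mast cell, erythroid, nerve and Schwann cell, intestine and liver, and sex-linked lists had fewer than 4 members above the floor.

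Among the lists tied to amino acid supply, targets of ATF4, the transcription factor of the amino acid stress response, had a median of −0.01 over 24 members, 12 positive and 12 negative. Asparagine synthetase (Asns) had 0.01 and Atf4 itself −0.06. Ddit3 was at least 1.86-fold higher and Trib3 at least 1.35-fold lower, each with the gene at the floor on 1 array, and the median over probe sets of Trib3 was 0.05. That median was −0.16 for Asns and 0.08 for Atf4. Psph, of serine synthesis, had −0.65 and Ddit4, an inhibitor of mTORC1, 0.56. Aminoacyl-tRNA synthetases had a median of −0.14 with 17 of 19 members negative, among them Farsa (−0.56) and Eprs (−0.48, but 0.04 as the median over its probe sets), at percentile 4.88. This list stood apart as lower with the median over probe sets (−0.16) and without probe sets of a sharing suffix (−0.20). Threonine, glycine and one-carbon metabolism had a median of 0.05 and did not stand apart, but with the median over probe sets it stood apart as higher, at 0.17. Medians were −0.06 for amino acid transporters, −0.03 for cytosolic ribosomal proteins and −0.06 for translation factors. Genes of mTORC1 and amino acid sensing had a median of 0.13 over 20 members, at percentile 98.0. Sesn3, a sestrin, had 0.92 and Mtor 0.54, but the list stood apart under only 2 of 8 alternatives.

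Genes of the unfolded protein response, which serve folding in the endoplasmic reticulum, had a median of −0.14 with 17 of 22 members negative, at percentile 0.64. The chaperone genes Hsp90b1 and Calr had −0.46 and −0.41, and Creld2 had −0.50. The sensor gene Ern1 had 0.42, and a further probe set of Hsp90b1 gave 0.07. Oxidative phosphorylation had a median of −0.10 with 48 of 66 members negative, at percentile 0.80, with Atp5k at −0.76, Ndufv1 at −0.62 and Ndufb1 at least 1.90-fold higher. Each of these lists lost its standing under 1 of 8 alternatives. Circadian clock genes had a median of 0.28 over 14 members, at percentile 97.9, with Nfil3, Ciart and Dbp at 0.76, 0.72 and 0.70 and Cry2 at −0.49. The first 2 of these were at the floor in the control pool, Cry2 was at the floor in the other, so these values are bounds, and Dbp had −0.15 without probe sets of a sharing suffix. The list stood apart under 4 of 8 alternatives.

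The other lists did not stand apart. Medians were −0.06 for glycolysis and gluconeogenesis, −0.03 for insulin and growth factor signalling, −0.17 for DNA damage, growth arrest and apoptosis, and 0.14 for cell cycle. They were −0.08 for DNA and histone methylation enzymes, −0.02 for imprinted genes, −0.03 for antioxidant and NRF2 targets, and −0.01 for heat shock proteins and chaperones. The DNA damage list stood apart as lower with no floor (−0.26) and the heat shock list as higher with the median over probe sets (0.13). Immediate early genes had −0.10, interferon response genes 0.14 (above the random range under 3 of 8 alternatives), acute phase and innate immune genes −0.06, proteasome genes −0.10, and autophagy and lysosome genes −0.11. Low members of these lists included Peg3 (−0.74), an imprinted gene, and the lysosomal protease gene Ctsd (−0.55). High members included the transcription factor gene Jun (0.75) and the co-chaperone gene Bag3 (0.68).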

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

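The tests of probe noise by pairs of probe sets and by the percentiles of second lists were chosen after their results were seen. So was the rule that a test with more than 50% of its members within 2-fold of the floor decides only if at least 4 brighter members all go 1 way and give the same verdict, which was set and then revised after the values given here had been computed. That rule was not applied to the percentile of the second adipocyte list, which is set against lists matched on signal. The other tests had their bounds written after the list medians and member values had been seen, but before the values they measure.

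Control probe sets for the tissue's own transcripts were not used in the gene comparisons. The control probe sets for 18S ribosomal RNA had log2 ratios of 0.59 for the 3' end, 0.39 for the middle and 0.11 for the 5' end, all higher in the threonine-deficient pool. Of the other such probe sets above the floor on at least 1 array, 3 lay outside the range of the added control transcripts: murine B1 at −0.62 (29969 to 19500), the MA probe set of pyruvate carboxylase at 1.93 (171 to 652, below the floor in the control pool), and its 5' probe set at −0.49 (380 to 269). The 18 hybridisation controls had a mean of −0.09 with a standard deviation of 0.09 across probe sets.

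Adipocyte markers were lower in the threonine-deficient pool. An intensity trend of the arrays was argued against, since the list median was still −0.906 after the loess trend was removed. A smaller share of adipose tissue in that pool stays open: 18 other adipocyte genes had a median of −0.369 at percentile 0.00, which is between the bounds set for and against it, with 10 of them near the floor and a median of −0.50 among the 8 brighter. That percentile argues against probe noise independent between genes as the whole cause. The random lists were matched on signal and carry the same noise, near the floor too. Of the 8 brighter genes, 7 were negative and 1 positive. How far noise adds to the size stays open: the 4 other probe sets of the listed genes had a median of −0.348, 4 of 4 negative. These values suggest a difference in attached fat at dissection or in fat within the organ as a hypothesis, and an effect of the maternal diet stays among the open explanations, as untested.

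Islet hormones were lower in the threonine-deficient pool. The median of −0.295 after removal of the loess trend argued against an intensity trend. A second list of 12 endocrine genes had a median of 0.175 at percentile 75.5, which excludes no probe noise, and other probe sets of islet genes a median of 0.070; by the bounds written first, these would have counted against a smaller share of islet RNA and in favour of probe noise. Those bounds are set aside here because 9 of the 12 genes and 5 of the 8 probe sets were near the floor, where probe set errors are larger than among bright genes. The 3 brighter genes and 3 brighter probe sets had medians of 0.18 and −0.39, too few to decide. These 3 probe sets all read Iapp, itself a member of the hormone list, so they speak for that gene only. Fewer islets in the pool, probe noise and an effect of the maternal diet, the last untested, therefore cannot be told apart.

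Genes at least 2-fold apart may in part reflect probe noise, since the ratios of 2 probe sets of 1 gene correlated with an r of only 0.059. Draws from the differences between probe sets gave 66.7 genes at least 2-fold apart and above the floor on both arrays, with 48 to 88 in 100 draws, against 123 observed. Second probe sets of 30 such genes had the same sign in 19. They were at least 2-fold apart the same way in 2 and the opposite way in 2. How many of the 2-fold genes differ between the pools therefore stays open. For the 2-fold genes as a set, cross-hybridising probe sets were argued against. Those ending in _s_at or _x_at read 12.5% of the 2-fold genes and 11.2% of all genes above the floor, a ratio of 1.12. Among genes named for size, they read Clcn5, Polh, Siah1a, Sapcd2, Muc13, Mapk1ip1, Dennd6b and Amhr2 on the higher side. On the lower side they read only Phldb1. For these single genes, sharing between transcripts stays open. Differences between animals and between the diets could not be separated from each other with 1 pool per group.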

How the results depend on the processing

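All alternatives were chosen in advance. No paired analysis was possible because each group had 1 sample, and for the same reason no sample could be left out. Adipocyte markers (medians from −0.98 to −0.45), islet hormones (−0.48 to −0.29) and acinar enzymes (0.10 to 0.14) stood apart under 8 of 8 alternatives. The counts of higher and lower genes followed the floor: 2559 and 1951 with no floor, 341 and 206 at the 50th percentile, 23 and 23 at the 75th, and 86 and 52 with a pseudocount. Of the last, 35 and 28 were among the genes first counted. With median centring they were 144 and 88, and with loess 128 and 126, of which 124 and 94 were shared. Alpha cell markers did not stand apart with no floor (−0.2579) or the median over probe sets (−0.1284), oxidative phosphorylation with the latter (−0.0779), nor the unfolded protein response without probe sets of a sharing suffix (−0.1261). The clock list did not with no floor (0.2443), the 50th percentile (0.2835), a pseudocount (0.1819) or without sharing suffixes (0.1999). The mTORC1 list did not with loess (0.0765), no floor (0.1221), the 75th percentile (0.1047), a pseudocount (0.0697), the median over probe sets (0.0166) or without sharing suffixes (0.0567). The cause was not tested. In 14 cases another list stood apart, 4 of them endocrine secretory machinery (lower), 3 interferon response (higher), 2 aminoacyl-tRNA synthetases (lower), and 1 each cholesterol synthesis and DNA damage (lower) and acinar regulators, heat shock and one-carbon metabolism (higher). Of the values of 218 genes under the alternatives, 1508 stayed within the local spread, 136 moved by more, and 2 values of a gene at least 2-fold apart reversed, both for Dennd6b (−0.0487 with the median over probe sets and without sharing suffixes), whose other probe sets went the other way. In all, 25 of the 218 genes had another sign under at least 1 alternative. Alternatives that left too few members or no probe set gave no value, as for alpha cell markers without sharing suffixes. Signal over background limits precision: over 4 groups of genes from the dimmest to the brightest second probe sets, the error per probe set was 0.39, 0.41, 0.30 and 0.22.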

Other observations

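The test in this part had its bound written before its value was seen, but the rule on members near the floor was set, and then revised, afterwards.

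Members of the immune lists went both ways. Macrophage and dendritic cell markers, 7 positive and 4 negative, did not stand apart. The macrophage genes Adgre1 and Csf1r had log2 ratios of 0.67 and 0.51, while Lyz2 had −0.43. Of the interferon response genes, 6 were positive and 5 negative. Among them Oas1a was at least 1.89-fold higher, Rsad2 had 0.81 and Gbp2 −0.51, with 0.10 for Gbp2 without probe sets of a sharing suffix. The interferon list did not stand apart, but did so as higher with no floor (0.40), with the floor at the 50th percentile (0.26) and with a pseudocount (0.21). Of the 3 sex-linked genes above the floor, all on the Y chromosome, Uty had −0.29 (0.03 as the median over its probe sets), Kdm5d −0.05 and Eif2s3y −0.04.

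Antibody-secreting cells were examined because Ighm, Mzb1 and Jchain were lower in the threonine-deficient pool. A hypothesis of fewer plasma cells was tested on 12 other plasma cell genes, whose median was 0.061, with 7 positive and 5 negative. By the bound written first this would have counted against fewer plasma cells. That bound is set aside because the members went both ways, from −1.07 for Iglv1 to at least 0.72 for Igkv9-120, which was at the floor in the control pool, and 7 of the 12 were near the floor. The 5 brighter genes also went both ways, with Igha at 0.13, Txndc5 at 0.07, Edem2 at 0.05, Sdc1 at −0.57 and Igkv8-30 at −0.60. Txndc5 and Edem2 serve secretion in other cells too, and the hypothesis stays open.

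Beta-actin and Gapdh control probe sets were read at both ends of the transcript. The log2 ratio at the 3' end minus that at the 5' end was 0.07 for beta-actin and −0.23 for Gapdh. The 3 probe sets of each had mean log2 ratios of 0.33 and −0.22.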
